A study of Papio anubis with 3 samples.

How the data were processed

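The study profiled 2 histone marks by chromatin immunoprecipitation sequencing (ChIP-seq) in neural progenitor cells of the subventricular zone of an adult olive baboon (Papio anubis), 1 library per mark. Per the labels' protocols, freshly dissected tissue was dissociated and cells were captured on beads with antibodies to markers of neural stem cells and neuroblasts (examples given are Nestin, GFAP and Doublecortin). The cells were then fixed in 1.1% formaldehyde and their chromatin was sheared to 200 to 500 bp. Antibodies to H3K27me3 and H4K20me3 gave the 2 profiles, and antibodies to total H3 and total H4 gave the libraries for normalization. The protocols state a depth of more than 200 M tags on a HiSeq instrument. The total H4 sample carries no peak list of its own here, and the total H3 library was not used here, so 2 of the 3 samples entered the comparisons.

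Reads were handled with Bowtie 1.1.1 and peaks with MACS2 2.1.0.20140616, per the submitters' processing notes, which give no parameters in the sources used here. The lists name papAnu2 as the genome, per the file names, with coordinates counted from 0 in the files and from 1 in the text. The H3K27me3 list has the broad-peak layout and the H4K20me3 list the narrow-peak layout of MACS2, so the caller mode, the control and the mark change together between the lists. Each deposited list holds the caller's fold enrichment over control, which is a ratio and the authors' own value for the peak. In a broad list of this caller the fold is a mean over the region and in a narrow list it belongs to the summit. Each deposited list also gives -log10 p and -log10 q values by the caller. The deposited score column equals the whole part of 10 times the -log10 q in every row of both lists and was not used further. The largest q was 0.0963 in the H3K27me3 list and 0.0482 in the H4K20me3 list. Peaks are numbered in file order without a gap in both lists. The peak names carry several run-like names and further tags that the sources used here do not explain. Whether sequencing runs were pooled, and whether reads that map to many places were kept, is therefore unknown, which limits what deep control coverage can be taken to mean. Read counts per library were not used here, so the depth behind each list is unknown apart from the control pileups described next.

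The control value that the caller set against a peak, called its control pileup here, was solved from the fold and p of the peak. The fold was taken as (ChIP pileup + 1) / (control pileup + 1) and p as the upper tail of a Poisson distribution. The solved control values are not whole numbers (lowest 3.50 for H4K20me3). They are expected values on the caller's scale and not raw counts of control fragments under the peak. In the H4K20me3 list all 10000 ChIP pileups recovered in this way were whole numbers within a tolerance of 0.02. In the H3K27me3 list, where folds are means over a region, 5.78% were, so its control pileups are approximate. A peak was called deep in control where its control pileup exceeded 2 times the lowest in its list (limits of 10.4 for H3K27me3 and 7.00 for H4K20me3), and ordinary otherwise. On 2000 simulated peaks the solved control pileup was within 0.00151% of the true one. These peaks had whole ChIP pileups and followed the formula exactly, so this covers rounding only. It does not give the accuracy in the H3K27me3 list, where folds are means over a region.

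Overlaps of at least 1 bp were counted between the lists. The expected count came from 10000 rotations of 1 list along each chromosome, which keep widths and clustering. Chromosome lengths were replaced by the largest peak end in either list, called the span here (2659 Mb over 21 chromosomes), since no genome of this build was used. Rotation does not avoid assembly gaps, so the expected counts are somewhat low. The overlap test was tested on lists made by rotating the H3K27me3 list at random along each chromosome against the H4K20me3 list. Of 100 such draws, 1 gave an overlap reached by fewer than 0.05 of the rotations. With 100 planted overlaps the mean excess over rotation was 98.1 (range 96.6 to 101 over 20 draws). These draws used the same rotation as the test, so they check its computation only. They do not cover assembly gaps or deep coverage shared by both libraries. Peaks less than 50 kb apart were joined into clusters, and the largest cluster was compared with 1000 random placements of as many peaks per chromosome. Shares carry exact (Clopper-Pearson) 95% intervals and the limit that a count of 0 allows is 3 counts; both cover counting error only, and neighbouring peaks are not independent. With 1 library per mark there is no replicate check, and no p-value compares the marks. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures by matplotlib 3.10.9.

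The overlap test, its alternative overlap rules and thresholds, the joining of neighbouring peaks and the share of peaks on chromosome X were fixed before the data were examined, as was the rule for single peaks named in the text (the 5 of highest fold and the 5 widest in each list). The cluster distance, the clusters and chromosomes named, the deep and ordinary control classes and the analysis of chromosomes without peaks were chosen after seeing the data. Planned results on promoters, gene lists, exons and introns, GC content and repeats were not run, because the only gene table used here belongs to another assembly (Panubis1.0) and coordinates were not carried between builds. No gene is therefore named as marked, and where peaks lie relative to genes, repeats or centromeres was not analysed here.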

Results

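Genomic positions of 2 repressive histone marks were obtained from neural progenitor cells of the baboon subventricular zone, a layer along the lateral ventricles that holds neural stem cells in the adult brain. H3K27me3 is the mark laid down by Polycomb repressive complexes, and H4K20me3 is a mark of constitutive heterochromatin. The H3K27me3 list held 709 peaks that covered 561 kb, with a median width of 582 bp (95% interval 546 to 638) and a range of 198 to 7719 bp. The H4K20me3 list held 10000 peaks that covered 4035 kb, with a median width of 292 bp (95% interval 289 to 296) and a range of 213 to 5554 bp. The authors' fold over control had a median of 2.71 and a maximum of 3.61 for H3K27me3, and a median of 3.86 and a maximum of 9.29 for H4K20me3. Each mark was measured in 1 library, so no value below has a replicate error. The H3K27me3 list was called in broad mode and the H4K20me3 list in narrow mode, which limits any direct comparison of numbers, widths and folds between the marks.

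The first comparison asked where along the chromosomes each mark lies. A large part of the H4K20me3 peaks lay in a small number of dense clusters. Of the 10000 peaks, 5914 (59.1%) fell in 29 clusters of at least 50 peaks on 14 chromosomes, which took up 14.3 Mb or 0.537% of the span. The largest cluster ran from 20657491 to 22613235 on chromosome 19 and held 1177 peaks with a median fold of 4.36, and peaks covered 32.1% of its length. The largest cluster in 1000 random placements of as many peaks per chromosome held 166 peaks, and the median of the largest was 72. Each of these was the largest over all chromosomes together, and peaks were densest on chromosome 19 (51.6 per Mb, next 10.3 on chromosome 20). Where peaks are as dense as on chromosome 19, the limit of 50 peaks alone therefore does not set a cluster apart from random placement. No separate limit was computed for the less dense chromosomes. Further large clusters held 668 peaks on chromosome 8 (41516457 to 43091796), 613 on chromosome 6 (45285768 to 46302362) and 431 on chromosome 3 (53962519 to 54933742). Others held 428 on chromosome 20 (27958384 to 29059408) and 312 on chromosome 11 (34204002 to 34766639). On chromosome 6 a separate cluster of 143 peaks lay between 134580365 and 134930913. The median control pileup was 4.16 in clusters of at least 10 peaks and 4.11 at peaks with no neighbour within 50 kb. Both lay near the lowest in the list (3.50), so thinner control in either group could hardly show. Clusters also differed among themselves. Those of 312 to 1177 peaks named above had medians of 3.59 to 4.39, while one of 119 on chromosome 19 had 13.2 and one of 58 on chromosome 9 had 48.8. The median fold was 3.998 in clusters of at least 10 peaks and 3.61 at peaks with no neighbour.

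**Figure D1:**
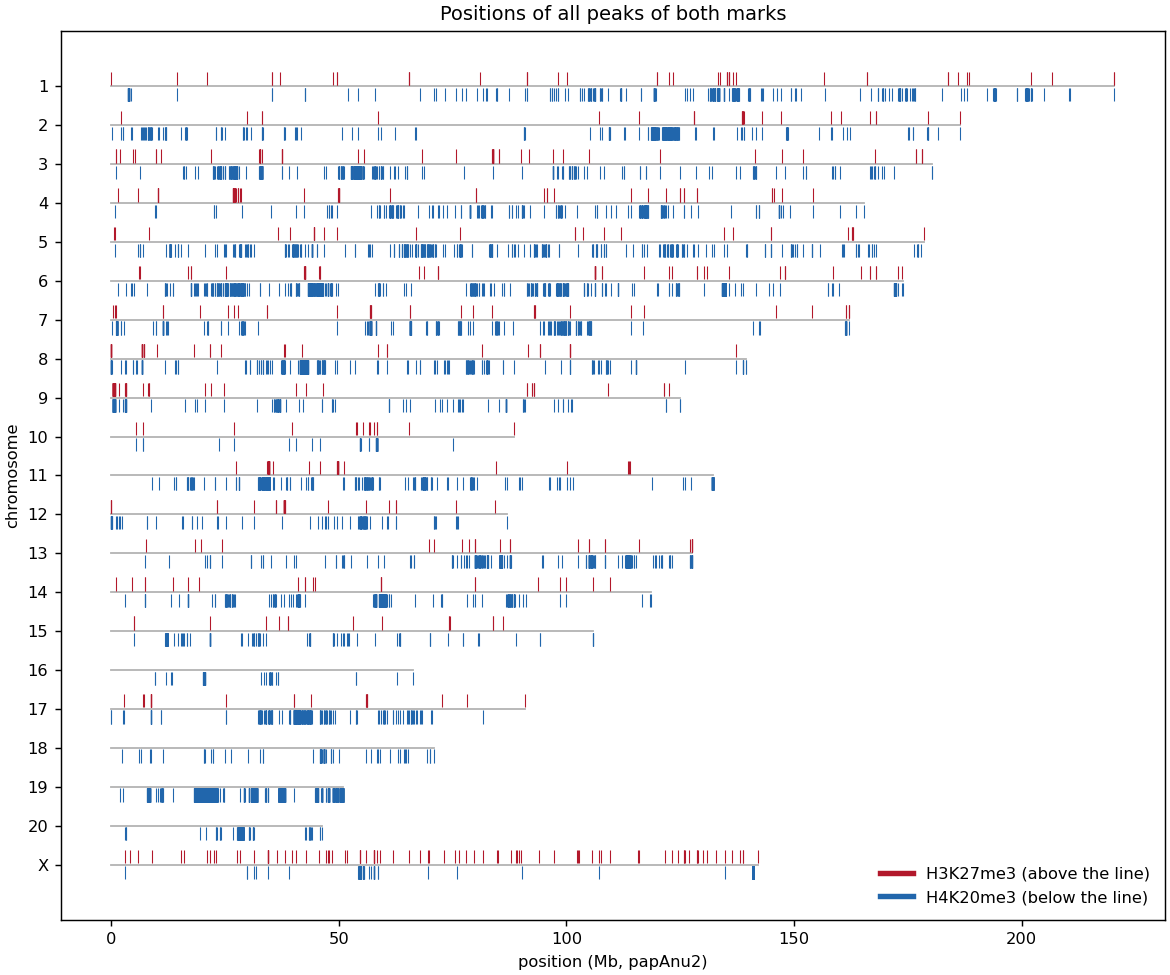
Positions of the 709 H3K27me3 peaks (red, above each line) and the 10000 H4K20me3 peaks (blue, below) along 21 baboon chromosomes, with position in Mb of papAnu2 on the x axis and chromosome on the y axis. H4K20me3 peaks pile up in dense blocks, the largest on chromosome 19, and chromosomes 16, 18, 19 and 20 carry no H3K27me3 peak.

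Chromosome 19 stood out for H4K20me3. It held 2630 peaks, or 26.3% of the list (exact 95% interval 25.4 to 27.2), against 1.92% of the span, a 13.7-fold excess. Of these peaks, 2313 lay in 12 clusters of at least 50 peaks, including 294 between 19668900 and 20565126, 268 between 31173455 and 32088559 and 119 between 36824454 and 37090910. Counted as clusters and single peaks together, chromosome 19 held 64 of 1980 (3.23%). At its 51.6 peaks per Mb, joining within 50 kb merges many peaks even when they are scattered, so this count alone does not show dense blocks. Its clusters of 1177, 294 and 268 peaks were larger than any in random placements (at most 166), and the one of 119 was not. Chromosome 20 held 4.75% of the peaks against 1.74% of the span, and chromosome 6 held 12.3% against 6.54%. Their shares of the clusters and single peaks were 1.31% and 10.8%. A single block held 428 of the 475 peaks on chromosome 20. By number of peaks relative to span, H4K20me3 was sparsest on chromosome 10, with 0.530% against 3.33%. Next came chromosome 12 with 0.780% against 3.27%, chromosome 16 with 0.610% against 2.496% and chromosome 18 with 0.770% against 2.67%. The order differed for clusters and single peaks, where chromosome X was lowest (1.06% against 5.34%, with the limit on X given below). Chromosomes 12 and 18 held 2.78% and 2.22% of these. The strongest single peaks lay in the blocks named above. The highest folds were 9.29 at chromosome 19 position 21749645 to 21749996, 8.66 at chromosome 19 position 20863688 to 20864050 and 8.48 at chromosome 8 position 41969678 to 41970317. A fold of 7.996 was shared by 3 peaks, among them those at chromosome 11 position 34548797 to 34549817 and chromosome 19 position 21471815 to 21472426. None of these 5 overlapped an H3K27me3 peak. For those on chromosome 19 this was fixed in advance, since the H3K27me3 list holds no peak there. The widest H4K20me3 peaks were 5554 bp on chromosome 11 (34445849 to 34451402), 5434 bp, 5099 bp and 4783 bp on chromosome 19 (21758870 to 21764303, 21765841 to 21770939 and 21776763 to 21781545), and 5004 bp on chromosome 1 (98176746 to 98181749).

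**Figure D2:**
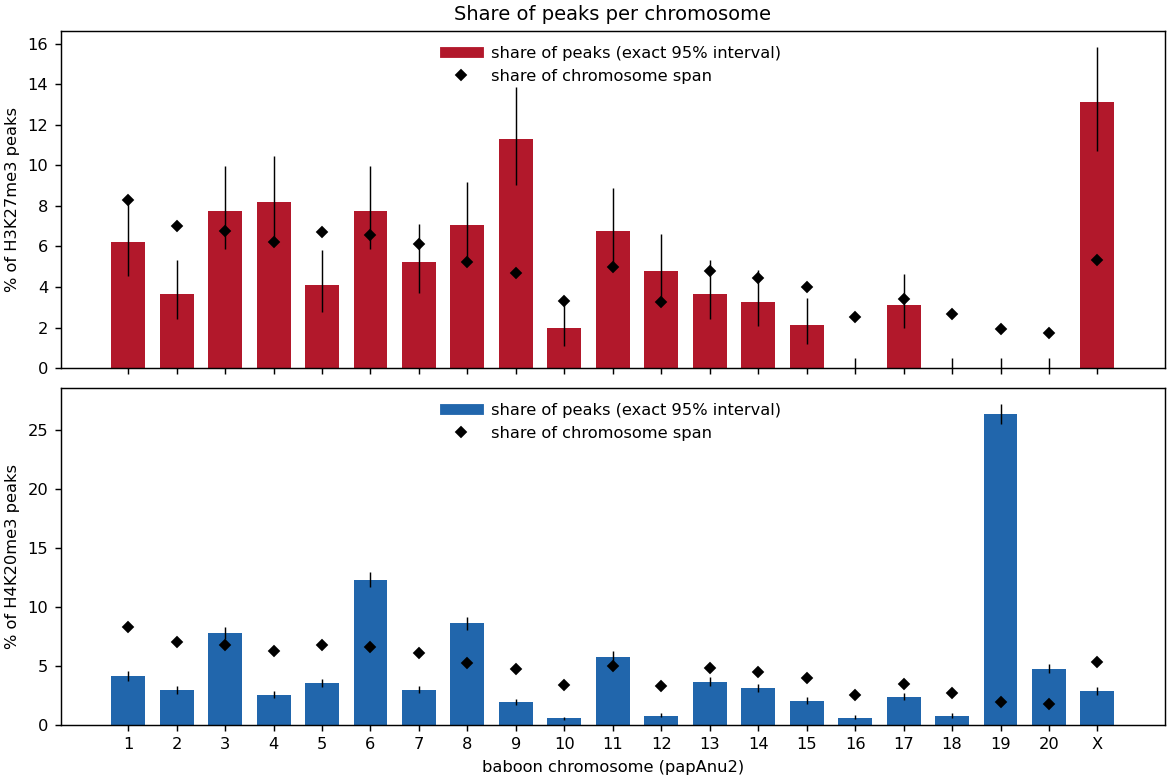
Percent of peaks on each chromosome (bars, with exact 95% intervals for counting error) and percent of the chromosome span (diamonds) for H3K27me3 (top) and H4K20me3 (bottom). Chromosome 19 holds 26.3% of the H4K20me3 peaks, and chromosome X holds 13.1% of the H3K27me3 peaks and 2.82% of the H4K20me3 peaks against 5.34% of the span.

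By number of peaks, H3K27me3 was in excess on chromosomes X and 9, and with neighbouring peaks counted once the excess remained on X but not on 9. Of the 709 peaks, 292 (41.2%) had no neighbour within 50 kb, and 139 lay in 8 clusters of at least 10 peaks. The largest cluster held 51 peaks, against at most 4 in 1000 random placements, so this list was clustered beyond chance as well. Chromosome X held 93 peaks, or 13.1% (exact 95% interval 10.7 to 15.8) against 5.34% of the span, while it held 2.82% (2.504 to 3.16) of the H4K20me3 peaks. The H4K20me3 list holds exactly 10000 peaks and its last peak closes a dense block of X, so its share there is a lower limit if the list was ended at that number. Counted as clusters and single peaks together, so that neighbours count once, X held 78 of 390 for H3K27me3 (16.1% to 24.3%) and 21 of 1980 for H4K20me3 (0.658% to 1.62%). The H3K27me3 excess on X lay in peaks with ordinary control coverage, of which X held 73 of 376 (19.4%, 15.5 to 23.8). Among peaks deep in control it held 20 of 333 (6.01%, 3.71 to 9.12), an interval that includes the share of the span. On chromosome 9 the excess was nearly as large, with 80 peaks or 11.3% (9.05 to 13.8) against 4.70% of the span, but 61 of these were deep in control. Among peaks with ordinary control, chromosome 9 held 5.05% (3.07 to 7.78). Of the 390 clusters and single peaks it held 18 (4.62%, 2.76 to 7.20), so its excess lay in neighbouring peaks. Chromosomes 4, 8, 11 and 12 held 1.32 to 1.46 times their share of the span, and among peaks with ordinary control chromosomes 4 and 12 held 1.93 and 2.03 times theirs. With neighbours counted once, chromosomes 4, 8, 11 and 12 held 1.11, 0.879, 0.722 and 0.940 times their share of the span. On chromosome 12 a single cluster held 17 of the 34 peaks. The 73 peaks on X were spread over 14 of the 15 stretches of 10 Mb on X, with at most 10 in any stretch. Their median fold was 2.90, against 2.92 for peaks with ordinary control on the other chromosomes.

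The 8 H3K27me3 clusters with at least 10 peaks were of 2 kinds. In 3 of the 8, control coverage was ordinary, folds were high for this list and no H4K20me3 peak was present. These were a cluster of 17 peaks on chromosome 12 (38000321 to 38097853, median fold 2.99), one of 13 peaks on chromosome 3 (83728576 to 83834732, median fold 2.94) and one of 12 peaks on chromosome 11 (49694997 to 49809481, median fold 2.98). The other 5 of the 8 had median folds of 1.69 to 2.03, median control pileups of 30.7 or more and H4K20me3 peaks within them. Fold and control are not separate features of the 2 kinds. The lowest H3K27me3 fold listed was 2.42 at ordinary control and 1.37 at deep control, so lower folds could be listed only in the second kind. Among smaller clusters, one of 9 peaks on chromosome 6 (42434968 to 42527499, median fold 2.96) had the features of the first kind. Some fitted neither kind, with deep median control but no H4K20me3 peak. Examples are 6 peaks on chromosome 6 (106265575 to 106305277, control 27.5) and 6 on chromosome 4 (26657185 to 26672874, control 12.7). The largest of the 8 clusters, of the second kind, was a stretch of 51 H3K27me3 peaks on chromosome 9 (373060 to 767299). It had a median fold of 1.76 and a median control pileup of 54.6, and also held 80 H4K20me3 peaks. No H3K27me3 peak was listed on chromosomes 16, 18, 19 and 20, which make up 8.82% of the span. A count of 0 in 709 peaks allows a share of up to 0.423% for each of them. The same 4 chromosomes held 3243 H4K20me3 peaks.

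The peaks of highest H3K27me3 fold all had ordinary control coverage and no H4K20me3 peak. Their folds were 3.61 at chromosome 13 position 127190713 to 127191046, 3.51 at chromosome 17 position 7061302 to 7061550, 3.47 at chromosome 4 position 26956679 to 26956903, 3.44 at chromosome X position 90086893 to 90087140 and 3.44 at chromosome 11 position 49775875 to 49776072. The last of these lies within the cluster of 12 peaks on chromosome 11. The 5 widest H3K27me3 peaks, in contrast, all overlapped H4K20me3 and were deep in control. They measured 7719 bp on chromosome 11 (34739905 to 34747623, fold 1.60, control pileup 110), 6178 bp on chromosome 6 (25167314 to 25173491, fold 1.64), 5600 bp on chromosome 1 (98176048 to 98181647, fold 1.66), and 5350 bp and 5072 bp on chromosome 9 (3078681 to 3084030, fold 1.496, and 759596 to 764667, fold 1.45).

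The second comparison asked whether the marks share positions. Of the 709 H3K27me3 peaks, 224 (31.6%, exact 95% interval 28.2 to 35.2) overlapped an H4K20me3 peak by at least 1 bp. Rotation of the lists gave 2.003 on average and at most 27 in 10000 rotations, so the overlap was 112 times the expected count and no rotation reached it. Seen from the other list, 305 of the 10000 H4K20me3 peaks (3.05%, 2.72 to 3.41) overlapped H3K27me3. This share is low in part because 3243 of the 10000 lay on chromosomes without an H3K27me3 peak and could not overlap. Shared positions were found on all 17 chromosomes with H3K27me3 peaks and fell into 121 regions.

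Nearly all of the overlap lay where control coverage was deep. Among H3K27me3 peaks deep in control, 218 of 333 (65.5%, 60.1 to 70.6) overlapped H4K20me3, while among those with ordinary control 6 of 376 (1.60%, 0.588 to 3.44) did. The count of 6 was above the 0.896 expected by rotation and was reached in 108 of 10000 rotations, and 5 of the 6 lay on H4K20me3 peaks deep in control. With ordinary control in both lists a single H3K27me3 peak overlapped, against 0.734 expected by rotation, and 4583 of 10000 rotations reached that count. With folds of at least the median required in both lists, 1 of 355 H3K27me3 peaks overlapped, against 0.454 expected. That cut is not a separate line of evidence. It lies at a fold of 2.71 for H3K27me3, where peaks deep in control had a median of 1.84, so it largely repeats the split by control. Overlapping H3K27me3 peaks had a median fold of 1.76 (quartiles 1.60 to 1.96), a median control pileup of 61.4 and a median width of 796 bp. The other H3K27me3 peaks had a median fold of 2.86 (2.63 to 2.99), a median control pileup of 6.18 and a median width of 535 bp. In the H4K20me3 list the overlapping peaks had a median fold of 2.501 and a control pileup of 58.2, against 3.88 and 4.09 for the rest. The rest include the 3243 peaks on chromosomes without an H3K27me3 peak. The caller's -log10 q went the other way from the fold and was higher at overlapping peaks. Its median was 2.75 against 1.46 for the rest in the H3K27me3 list, and 17.9 against 4.61 in the H4K20me3 list. At ordinary control coverage the lowest fold listed was 2.42 for H3K27me3 and 2.44 for H4K20me3, so co-occurrence at lower folds was not detectable there.

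**Figure D3:**
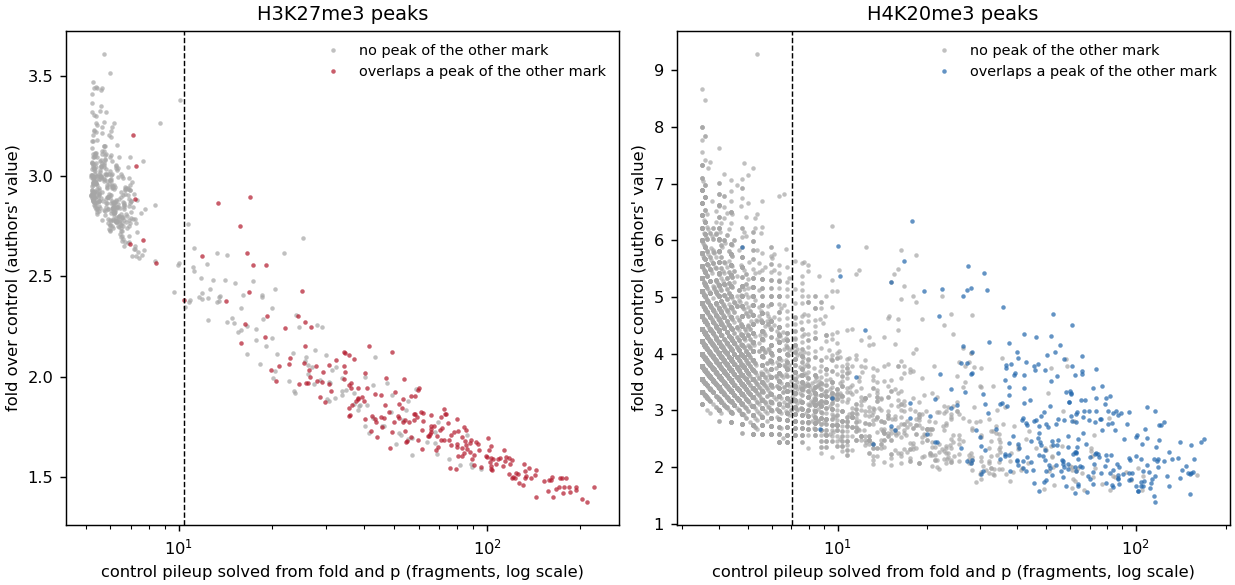
Fold over control (authors' value, y axis) against the control pileup solved from fold and p (x axis, log scale) for each H3K27me3 peak (left) and H4K20me3 peak (right), with peaks that overlap the other mark in colour and the limit between ordinary and deep control as a dashed line. Of the 224 overlapping H3K27me3 peaks 218 lie right of the line, as do 304 of the 305 overlapping H4K20me3 peaks.

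The shared regions with the most peaks lay on chromosomes 9, 11 and 8. On chromosome 9 the stretch from 373060 to 621997 held 20 overlapping H3K27me3 peaks (median fold 1.68) and 33 overlapping H4K20me3 peaks (median fold 1.95). On chromosome 11 the stretch from 34693585 to 34766639 held 13 and 21 such peaks, with median folds of 1.69 and 3.06. That stretch is the end of the H4K20me3 cluster of 312 peaks, in which 25 H3K27me3 peaks were found. A stretch at the very start of chromosome 8 (2 to 48742) held 7 and 10 such peaks, with median folds of 1.63 and 2.08. On chromosome X the stretch from 57637896 to 57651687 held 6 and 9 such peaks, with median folds of 1.78 and 3.28. Of the 29 H4K20me3 clusters with at least 50 peaks, 16 lay on chromosomes with H3K27me3 peaks, and 9 of these held any. The counts were 37 on chromosome 9 (373191 to 621687), 25 on chromosome 11, 6 on chromosome 7 (56859241 to 57032158), 4 each on chromosomes X (54364496 to 54761895) and 14 (58871293 to 59300496), 3 in the cluster of 613 peaks on chromosome 6, and 1 each on chromosomes 8, 3 and 13. Without the clusters on chromosome 9 and chromosome 11 that held the most, the other 14 held 20 H3K27me3 peaks, or 3.10 per Mb against 0.292 per Mb over the 17 chromosomes. Of the 82 H3K27me3 peaks in the 16 clusters, 78 were deep in control, as were 18 of the 20 in the other 14 clusters.

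**Figure D4:**
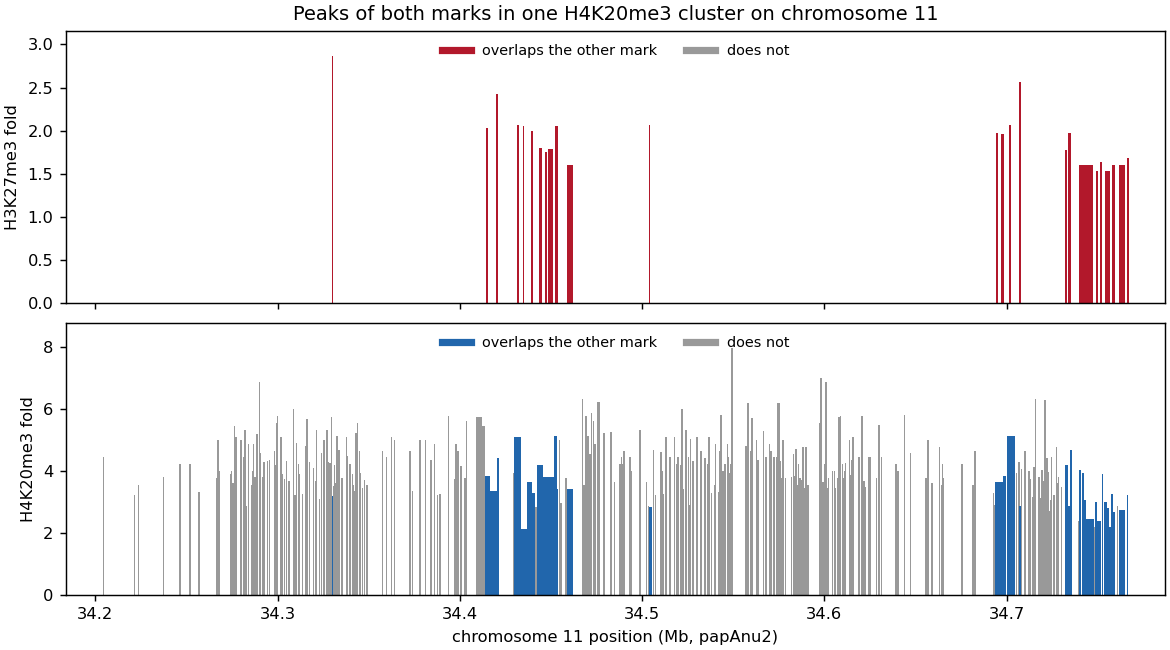
Fold over control (authors' value, y axis) of each H3K27me3 peak (top) and H4K20me3 peak (bottom) along the H4K20me3 cluster on chromosome 11 (x axis, Mb of papAnu2); bars span the peak, drawn at a minimum visible width, and coloured bars overlap the other mark. H4K20me3 peaks fill the cluster of 312 peaks, with folds up to 7.996, and the 25 H3K27me3 peaks within it reach at most 2.87.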

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

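The settings of control coverage, left-out chromosomes, cluster distance, clusters counted in place of peaks, and every alternative for chromosome 19 and for clusters were chosen after seeing the data; the others were fixed before. Of 74 alternative values, 44 kept their direction and side of the threshold or, where there was no test, stayed within 1.5 times (numbers, lengths, percent in clusters) or within the 95% interval (median widths, share on chromosome 19); 26 moved beyond these limits, 4 fell short of the threshold and 0 reversed. The overlap percent of H3K27me3 stayed far above rotation with 50% of the shorter peak required, with distances of 1 or 10 kb, with a -log10 q of at least 5 (54.5%, 6 of 11 peaks), with equal numbers of peaks, with random placement in place of rotation, and without chromosome 9, 11 or 19. It fell short of the threshold of 0.05 of the rotations with a fold of at least the median in both lists (0.282%, 1 peak against 0.454 expected), with ordinary control in both lists (0.266%, 1 against 0.748 in a further set of rotations) and with a control limit of 3 times the lowest (0.735%, 3 against 0.881). A -log10 q of at least 5 left 11 H3K27me3 peaks (5.30 kb, median width 356 bp) and 4415 H4K20me3 peaks (2386 kb, 404 bp). A fold of at least the median left 355 (224.0 kb, 541 bp) and 5001 (2309.8 kb, 350.0 bp). Joining H4K20me3 peaks within 1 kb gave 5799 and within 5 kb 3568 (10618 kb, 275 bp), and joining H3K27me3 peaks within 5 kb gave 1044 kb. Ordinary control left 376 H3K27me3 peaks (236 kb) and a median H4K20me3 width of 284 bp. The H3K27me3 share on chromosome X was 6.01% among peaks deep in control and 9.67% to 29.6% in the other settings, all above its span; the H4K20me3 share was 0.717% to 3.04%, below it in all, with no allowance for a list ended early on X. The H4K20me3 share on chromosome 19 was 31.9% at a -log10 q of at least 5, 32.3% at a fold of at least the median, 27.9% with ordinary control, 29.1% of covered bases and 3.23% of clusters. Clusters of at least 50 peaks held 48.6% of the H4K20me3 peaks with a cluster distance of 20 kb and 48.9% without chromosome 19, where there were 17 such clusters. Counts fell under stricter settings by construction; other causes were not tested. Leaving out unplaced scaffolds changed nothing because every listed peak is on a numbered chromosome or X. The other settings foreseen for promoter windows, gene lists, exons and introns, GC content and repeats were not run, for lack of an annotation of this build. No replicate could be left out with 1 library per mark, and depth limits the lowest fold that could be listed.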

Other observations

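On 8 of 21 chromosomes a single block held at least 50% of the H4K20me3 peaks. The block with the most peaks held 90.1% of the H4K20me3 peaks of chromosome 20, 77.8% of those of chromosome 8, 62.3% of those of chromosome 10 (58190490 to 58391663, 33 peaks), 55.7% of those of chromosome 3, 55.4% of those of chromosome 15 (12046524 to 12345073, 112 peaks) and 141 of the 282 on chromosome X (54364496 to 54761895). The lowest such shares were on chromosomes 2, 5, 12 and 17, with 7.85%, 10.8%, 11.5% and 13.7% of their peaks in the largest. The H4K20me3 list holds exactly 10000 peaks, and its last peak (141052254 to 141053364 on chromosome X) closes a dense block of 104 peaks that starts at 140929850. Beyond it lie 924 kb of X and 1 H3K27me3 peak, so whether the list was ended at that number is open. With 267 further H4K20me3 peaks there, the peak share of X would reach that of its span.

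The tests below were set out after their values or related ones had been seen, although the rotation of the lists was fixed before the data were examined. The first pattern is the overlap of the marks at deep control coverage, where chance placement is argued against, since 0 of 10000 rotations reached the overlap. Peaks with ordinary control in both lists overlapped at 1.36 times the rotated count (1 peak) and, with a control limit of 3 times the lowest, at 3.41 times (3 peaks, 733 of 10000 rotations as high). Ordinary control in H3K27me3 alone gave 6.69 times (6 peaks, 108 of 10000 rotations as high). That exceeds rotation, but 5 of the 6 lay on H4K20me3 peaks deep in control. Ordinary control in H4K20me3 alone gave 0.527 times (1 peak). Where control was ordinary in both lists, counts were too low to show or exclude a small excess. A candidate explanation for the bulk of the overlap is that these regions collect many reads in every library, for example where the assembly holds fewer copies of a repeat than the genome, and so let folds as low as 1.37 pass. Whether both marks also sit on the same nucleosomes there stays open. The folds over control exceed 1 for both marks, but every listed peak was selected for that, so they do not decide it. The handling of reads that map to many places is unknown, and no unmarked deep region was available for comparison.

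The second pattern is the lack of H3K27me3 peaks on chromosomes 16, 18, 19 and 20, the 4 of shortest span. Scattering the 390 clusters by span, with clusters taken as independent, gives 34.4 expected there. The probability of 0 is 2.93e-16 summed over all 5985 sets of 4 chromosomes, so chance is argued against. Elsewhere 304 of 1105 H4K20me3 peaks deep in control overlapped H3K27me3 (27.5%), and 288 of 418 with a control pileup over 20 did (68.9%); these 4 chromosomes hold 325 and 70 such peaks, with an overlap of 0 that follows from the empty list. Whether the chromosomes were left out when the H3K27me3 list was made stays open: a true lack of the mark would have to extend to these sites, which speaks against it only if the peaks there come from coverage and not from the mark, and that was left open above.

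The third pattern is the excess of H3K27me3 on chromosome X. Deep control coverage is argued against, since peaks with ordinary control were 3.64 times as frequent there as the span would give. A few crowded clusters are argued against, since the share of clusters with ordinary control was 5.05 times that of the span over the 17 chromosomes with peaks (71 of 240 clusters). Thin control coverage on X stays open. The median control pileup of X peaks with ordinary control was 5.83, within the range of 5.32 to 6.27 over 16 autosomes. This does not decide it, because such peaks were defined by control pileups from the lowest in the list (5.20) to the limit of 10.4. Their median could not fall below 5.20 on any chromosome, and control coverage of X outside listed peaks was not measured. No biological explanation was tested, because the labels give neither the sex of the animal nor a second animal.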
